A study of Marchantia polymorpha with 8 samples.

How the data were processed

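RNA of Marchantia polymorpha was hybridised to 8 arrays of a custom Agilent 2-colour design, each with mutant RNA in a channel and wild type RNA in the other. Per the labels' protocols, plants were grown on 0.5-strength Gamborg's medium with 1% agar for 2 weeks before OPDA treatment or 3 weeks before wounding. OPDA was given to 15-day-old plants in liquid medium for 2 h by the treatment protocol and 3 h by the design text, a difference that is not settled here, and wounded plants of 21 days were collected after 2 h. Each independent biological replicate held 6 to 8 plants, and 200 ng of RNA was amplified and labelled. There were 3 arrays of Mpmycy against Tak-1 under OPDA, 3 of Mpmycx against Tak-2 under OPDA and 2 of Mpmycy against Tak-1 after wounding. Per the labels, mutant RNA carried Cy3 in replicates 1 and 3 and Cy5 in replicate 2 of each group, so 5 arrays had the mutant in Cy3 and 3 in Cy5. Groups, replicate numbers and dyes were taken from the labels. No array of untreated plants was used, so that each value is a difference between genotypes within a treatment and not a response to it.

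The deposited scanner files hold a mean intensity and a median background intensity per spot and channel, made with Agilent Feature Extraction 10.7.3.1 per the file headers, before background subtraction and dye normalization. They also hold processed intensity values that the scanner software had background-subtracted with spatial and multiplicative detrending and normalized for dye by a linear and a lowess step, and the log10 ratio of processed Cy5 over Cy3, per the file headers. The deposited value table gives per spot a log2 ratio of mutant over wild type whose sign the authors had already turned on the dye-swapped arrays. Its direction and scale were found by comparison with the scanner values: per array the medians were 0.02 to 0.04, the correlations across probes with the ratios computed here were 0.992 to 0.997 and the slopes on the scanner ratio 0.761 to 0.822. Its background correction and normalization are not given in the sources used here. All 8 arrays lay on 1 slide and were read in 1 scan, so neither could be tested as a batch.

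Ratios were computed in R 4.3.3 with limma 3.58.1. Mean intensities were corrected with normexp and an offset of 50, normalized within each array by loess with control spots at weight 0, and turned to mutant over wild type. Control spots and spots with outlier flags (71 to 214 per array) were left out, no spot was saturated, and spots of the same probe were averaged. Of 40422 probes, 26055 were well above background on at least 2 of the 8 arrays in the mutant's or the wild type's channel and were kept. For each locus the brightest kept probe was used, which gave 13468 genes, 10134 of them with an Arabidopsis match in the array's description and 3334 without. Of the genes called, 12 of 2166, 39 of 3570 and 33 of 4390 with a further probe had that probe on the opposite side of 0, in the order Mpmycy under OPDA, Mpmycx under OPDA and Mpmycy after wounding. The RefSeq gene table matched 0 of 19217 loci, so that the locus names and descriptions of the array were kept.

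All 8 arrays were fitted together with limma's lmFit and eBayes, with a column for each group and a dye term, which gave 4 residual and 3.8 prior degrees of freedom. Differences between groups were contrasts of the same fit. P-values were adjusted by the Benjamini-Hochberg method over 13468 genes per comparison, and genes with an adjusted p under 0.05 were called. The dye term itself was called for 186 genes. The 32 gene lists were fixed before the data were examined, as words to be matched in the descriptions. Of these, 30 held genes, 29 held the 5 or more that camera was run on, with a preset correlation of 0.01 between genes, and the lists for oil bodies and for female organs matched 0. Word matches also brought in genes of other function, such as lipid phosphatases named PAP2 in the WRKY and AP2/ERF list, a ribosome recycling factor in the cell cycle list and BRK1 in the heat-shock list. Each list call was also computed with a correlation estimated from the residuals, under which no list passed in any comparison. The estimate rests on the 4 residual degrees of freedom. It was 0.202 for the peroxidase list but 0.01, the preset value, for the abscisic acid and desiccation list. After wounding the camera p of the latter list rose from 6.95e-08 to 0.00569 all the same. The loss of calls therefore does not measure correlation between genes alone. Where a probe was not well above background on any array of the dimmer genotype, a bound is printed as "at least N-fold": the brighter genotype's mean against the dimmer genotype's mean of, per array, the higher of the lowest detected signal and the probe's own signal, after loess and Aquantile, which remains open to dye bias in the OPDA groups, whose swaps are not balanced. Overlaps expected for independent lists are products of the list lengths divided by the number of genes. Correlations across genes were computed on group means that weight both dyes equally and share no array. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

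Named genes followed a rule fixed before the data were examined. They are the loci with a MYC2 match, then up to 10 genes of largest rise and 10 of largest fall per comparison among called genes with the same sign on every array, a detected brighter channel on every array and a product description. To these came up to 4 called members of each list, or 2 where the list did not pass, and up to 10 jasmonate genes whether called or not.

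The steps were tested on simulated data with residual spreads of the real arrays, 13346 genes and 200 changed genes in similar numbers of 3 sizes. In the Mpmycy OPDA comparison 64.2%, 97.0% and 100% of genes changed by 0.5, 1 and 2 on the log2 scale were recovered, with 9 false among 183 calls. In the Mpmycx comparison 67.2%, 95.5% and 100% were recovered, with 9 false among 184, and after wounding 59.7%, 89.6% and 98.5%, with 6 false among 171. A list of 40 genes moved by -0.3 was found in each comparison, and 0 of 50 unmoved lists were called, in data simulated without correlation between genes.

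Because the groups share replicate numbers, their pairing was checked. Deviations from the group means of same-numbered OPDA arrays of the mutants correlated across genes at 0.115, 0.255 and 0.126 for replicates 1, 2 and 3, which meets the rule for paired numbers set beforehand (each over 0.1). Replicate 2 is however the dye-swapped array in every group, and the difference between replicates 1 and 3, which shares no dye effect, correlated at 0.034. A fit with the replicate number as a block in place of the dye term was therefore kept as an alternative. The other alternatives were no background subtraction, the scanner software's log ratio, median centring, the submitters' ratios, no filter and a stricter one, no dye term, a fit of the compared arrays alone, array weights, the mean of a gene's probes, a separate-channel fit, stricter thresholds, a rotation test of lists (fry) and leaving out each array in turn.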

Results

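Transcript levels were measured in the liverwort Marchantia polymorpha on 8 2-colour microarrays, each of which held RNA of a mutant and of its wild type, labelled with Cy3 and Cy5. The mutants Mpmycy (male) and Mpmycx (female) are named for MYC transcription factors, basic helix-loop-helix (bHLH) proteins that act in jasmonate signalling in flowering plants. Mpmycy was set against the male accession Tak-1 and Mpmycx against the female accession Tak-2. On 3 arrays each, both genotypes had been treated with 12-oxo-phytodienoic acid (OPDA), an intermediate of jasmonate biosynthesis, and on 2 further arrays Mpmycy and Tak-1 had been wounded with forceps. The RNA came from apical fragments of independent pools of 6 to 8 plants. Between 54.6% and 62.4% of the probes were well above background per channel and array, and the number of arrays limits the precision of every value. Errors given after ± are standard errors (SE) of log2 fold changes, mutant over wild type, from limma's fit, unless called SD. That fit pools the spread over all 8 arrays, so that errors and p-values after wounding do not rest on its 2 arrays alone. Genes carry the locus names of the array and are described by their best match in Arabidopsis, so that a name such as AOC3 stands for similarity only.

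The transcripts of the mutated genes were examined first. Of the 2 loci whose best match was the jasmonate regulator MYC2, MapolyY_B0018 had no probe well above background on any Tak-1 and Mpmycy array in either channel, so that its signals check nothing there. Mapoly0018s0019 was well above background in both channels of all 3 Tak-2 and Mpmycx arrays and on no Tak-1 and Mpmycy array. Its mean log2 ratios in Mpmycx were -0.27 ± 0.11 and -0.48 ± 0.10 (SD, n = 3) for its 2 probes, and the fitted change of the brighter probe was -0.25 ± 0.07 (adjusted p = 0.0347, over 0.05 under 7 of 13 alternatives with a range of 0.00745 to 0.379). Whether these probes lie in the part of the gene that the mutation affects is not given in the sources used here. The arrays did separate the sexes as labelled: 58.6% to 64.3% of the 70 probes of scaffold Mapoly0018s were well above background on Tak-2 and Mpmycx arrays and 20.0% to 27.1% on Tak-1 and Mpmycy arrays, whereas for the 255 Y-chromosome probes the shares were 5.9% to 8.6% and 16.9% to 20.4%.

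The comparison of Mpmycy with Tak-1 under OPDA asked which transcript levels depended on the male MYC gene while the hormone precursor was present. The steepest fall was that of a patatin-like lipase gene (Mapoly0106s0023), a family that releases fatty acids from lipids, at -6.99 ± 0.21, or 127-fold (n = 3, adjusted p = 2.46e-07). Genes for the enzymes that turn released fatty acids into OPDA fell as well: a PLAT/LH2 lipoxygenase gene (Mapoly0106s0031) 15.3-fold, an AOC3-like allene oxide cyclase gene (Mapoly0057s0049) 6.12-fold and an AOS-like allene oxide synthase gene (Mapoly0185s0014) 5.11-fold. A JAZ1-like gene (Mapoly0097s0021), whose Arabidopsis match encodes a repressor that binds MYC proteins, fell 4.68-fold (-2.23 ± 0.09, adjusted p = 1.31e-06). Changes of 2-fold or more were mostly falls: 311 genes were lower in Mpmycy by that much and 11 were higher.

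Among other genes with the steepest falls were those for a polyketide cyclase (Mapoly0021s0121, -5.24 ± 0.08), an alpha carbonic anhydrase (Mapoly0060s0019, -5.20 ± 0.13), the carotenoid-cleaving dioxygenase CCD1 (Mapoly0066s0017, -4.91 ± 0.14), a cupin (Mapoly0377s0002, -4.61 ± 0.17, with the mutant's signal well above background on 2 of 3 arrays) and a terpenoid cyclase (Mapoly0108s0042, -4.11 ± 0.10). Of 26 jasmonate biosynthesis genes 13 fell and 2 rose (13 and 3 adjusted over the list alone, camera adjusted p = 0.000702, adjusted p = 0.404 with an estimated correlation). They included a LOX3-like lipoxygenase gene (Mapoly0191s0014, -2.04 ± 0.09) and an ACX3-like gene (Mapoly0007s0119, -1.97 ± 0.08) for an acyl-CoA oxidase of peroxisomal beta-oxidation. The COI1-like receptor gene (Mapoly0025s0025) had a value of 0.13 ± 0.07 (adjusted p = 0.278) and the NINJA-like adaptor gene (Mapoly0005s0166) of -0.05 ± 0.08 (adjusted p = 0.752). Of 32 bHLH genes 11 fell and 3 rose (12 and 4 adjusted over the list alone, camera adjusted p = 0.0269, adjusted p = 0.404 with an estimated correlation). They included a TT8-like gene (Mapoly0028s0058, -3.92 ± 0.31) and Mapoly0013s0167 (-2.62 ± 0.10).

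Of the lists, that of peroxidases held the most falls in Mpmycy under OPDA: of 174 genes, 59 fell and 1 rose (78 and 5 adjusted over the list alone, camera adjusted p = 3.97e-09, adjusted p = 0.547 with an estimated correlation). Over the 4 other scalings 31 to 55 fell and 0 to 6 rose, and the list passed in each. The largest falls in this list were those of Mapoly0089s0042 (-1.68 ± 0.14), which matches the fatty acid dioxygenase DOX1, and of the peroxidase gene Mapoly0064s0029 (-1.36 ± 0.10). Of 67 phenylpropanoid and flavonoid genes 18 fell and 2 rose (23 and 3 adjusted over the list alone, camera adjusted p = 0.0037, adjusted p = 0.556 with an estimated correlation). Here chalcone synthase genes, which start flavonoid synthesis, had values of -3.57 ± 0.17 (Mapoly0070s0036, mutant signal well above background on 1 of 3 arrays) and -2.40 ± 0.24 (Mapoly0009s0178). Peroxidase and chalcone synthase genes form families of similar sequence, and cross-hybridisation between members leaves the value of a single member uncertain. Of 74 genes of the abscisic acid and desiccation list 18 fell and 5 rose (23 and 6 adjusted over the list alone, camera adjusted p = 0.0315, adjusted p = 0.404 with an estimated correlation). Late embryogenesis abundant (LEA) genes of this list stood at -0.92 ± 0.06 (Mapoly0016s0148) and -0.80 ± 0.05 (Mapoly0002s0220). The cytochrome P450 list did not pass (28 of 127 lower and 7 higher, adjusted p = 0.0533, range over the scalings 0.0189 to 0.13). It passed without background subtraction (0.046), with the scanner software's ratios (0.0233) and with the submitters' ratios (0.0189). A CYP94D2-like gene (Mapoly0023s0003) fell by 3.89 on the log2 scale.

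Increases of 2-fold or more in Mpmycy under OPDA were fewer than such falls. Of 25 glutathione S-transferase genes, whose products conjugate glutathione to reactive compounds, 9 rose and 1 fell (11 and 1 adjusted over the list alone, camera adjusted p = 0.00124, adjusted p = 0.404 with an estimated correlation). Over the 4 other scalings 4 to 11 rose and 0 to 1 fell, and the list passed in each. The list did not pass in Mpmycx (6 higher and 2 lower, adjusted p = 0.344) or after wounding (9 higher and 4 lower, mean -0.08, adjusted p = 0.546). The largest rises were those of a GSTU8-like gene (Mapoly0031s0032, 0.89 ± 0.13) and a GSTF10-like gene (Mapoly1812s0001, 0.66 ± 0.07). The heat-shock and chaperone list shifted upward, with 10 of 134 genes higher and 6 lower (5 and 4 adjusted over the list alone, camera adjusted p = 0.0315, adjusted p = 0.556 with an estimated correlation). The rotation test of lists (fry) did not pass it (adjusted p = 0.335). With median centring the list's calls were 0 higher and 3 lower, so that the balance of its calls turned. The risers were mixed: the largest was BRK1-like (Mapoly0132s0041, 0.58 ± 0.08), a match to a regulator of actin rather than a chaperone. Its call was lost with median centring (limma adjusted p = 0.0609) and without replicate 2 (0.0538). The largest fall of the list was that of a small HSP20-like gene (Mapoly0088s0083, -1.41 ± 0.07, mutant signal well above background on 2 of 3 arrays). The highest single increases were those of ankyrin repeat genes (Mapoly0035s0005, 1.75 ± 0.08, wild type signal well above background on 2 of 3 arrays, and Mapoly0035s0001, 1.69 ± 0.10) and of a FUT8-like fucosyltransferase gene (Mapoly0202s0006, 1.26 ± 0.11).

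In limma's test 2261 of 13468 genes differed between Mpmycy and Tak-1 under OPDA, 1430 lower and 831 higher. Median centring in place of loess gave 1042 genes and ended the calls of the abscisic acid (adjusted p = 0.256, range over the scalings 0.012 to 0.256) and heat-shock lists (0.187, range 0.0189 to 0.187), and fits without replicate 1, 2 or 3 gave 1141, 989 and 1209. Higher genes made up 36.8% of the calls, 50.8% with the scanner software's ratios, 58.5% with the submitters' ratios and 18.5% with median centring.

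**Figure D1:**
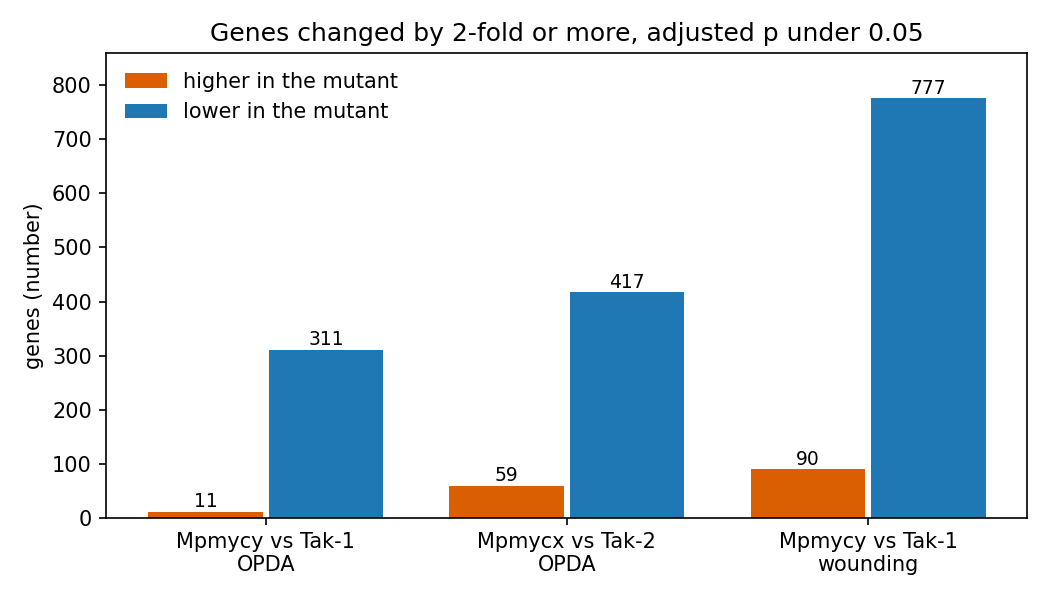
The vertical axis gives the number of genes that changed by 2-fold or more with a limma adjusted p under 0.05, in bars for genes higher and genes lower in the mutant, for each of the 3 comparisons. Lower genes outnumber higher ones in each, by 311 to 11, 417 to 59 and 777 to 90.

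The comparison of Mpmycx with Tak-2 asked the same of the female MYC gene under OPDA. The patatin-like gene Mapoly0106s0023 again had the steepest fall, at -6.45 ± 0.21 or 87.5-fold (n = 3, adjusted p = 5.11e-07), followed by the chalcone synthase gene Mapoly0070s0036 at -5.07 ± 0.17 or 33.6-fold, the carbonic anhydrase gene Mapoly0060s0019 at 28.9-fold and the cupin gene Mapoly0377s0002 at 26.9-fold. The lipoxygenase gene Mapoly0106s0031 fell 16.1-fold and the JAZ1-like gene changed by -2.30 ± 0.09 (adjusted p = 1.15e-06). The COI1-like gene stood at 0.09 ± 0.07 (adjusted p = 0.366). An NRT2.1-like nitrate transporter gene and an AMT2-like ammonium transporter gene fell in Mpmycx, and 5 genes similar to plasma membrane proton pumps rose. In all, 417 genes were lower by 2-fold or more and 59 higher.

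Of the 26 jasmonate biosynthesis genes 12 fell in Mpmycx and 2 rose (13 and 3 adjusted over the list alone, camera adjusted p = 0.000996, adjusted p = 0.457 with an estimated correlation). The AOS-like gene had a value of -2.25 ± 0.06, the AOC3-like gene of -2.0 ± 0.11, the ACX3-like gene of -1.97 ± 0.08 and the LOX3-like gene Mapoly0191s0014 of -1.81 ± 0.09. Of 3 transcription factor lists, those of bHLH and of WRKY and AP2/ERF genes passed, and the MYB list did not. Of 32 bHLH genes 14 fell and 5 rose (14 and 6 adjusted over the list alone, camera adjusted p = 0.00802, adjusted p = 0.553 with an estimated correlation). Here Mapoly0013s0167 stood at -2.88 ± 0.10 and the TT8-like gene at -4.16 ± 0.31. Of 35 WRKY and AP2/ERF genes 15 fell and 3 rose (15 and 4 adjusted over the list alone, camera adjusted p = 0.0186, adjusted p = 0.594 with an estimated correlation). WRKY42-like Mapoly0039s0030 (-2.37 ± 0.22) and ERF-1-like Mapoly0068s0088 (-1.58 ± 0.11) had the largest falls. The 3 risers of that list are lipid phosphatase and transporter genes that the search word AP2 had also matched.

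Of the 67 phenylpropanoid and flavonoid genes 30 fell and 9 rose (34 and 11 adjusted over the list alone, camera adjusted p = 0.000996, adjusted p = 0.594 with an estimated correlation). Of 33 dirigent, laccase and polyphenol oxidase genes, which act in phenolic coupling and oxidation, 16 fell and 2 rose (16 and 3 adjusted over the list alone, camera adjusted p = 0.000996, adjusted p = 0.594 with an estimated correlation). Dirigent gene Mapoly0117s0013 stood at -2.0 ± 0.21, and Mapoly0059s0071 was at least 3.61-fold lower (adjusted p = 6.39e-05), a bound given because the mutant's signal was not well above background on any array. Of 106 genes for nitrogen, sulfur, phosphate and iron uptake 42 fell and 16 rose (44 and 17 adjusted over the list alone, camera adjusted p = 0.00181, adjusted p = 0.594 with an estimated correlation). These included the NRT2.1-like nitrate transporter gene Mapoly0020s0040 (-2.76 ± 0.14, mutant signal well above background on 1 of 3 arrays), the AMT2-like ammonium transporter gene Mapoly0192s0010 (-2.06 ± 0.10) and the PHT2;1-like phosphate transporter gene Mapoly0054s0123 (at least 3.42-fold lower). Of the 74 abscisic acid and desiccation genes 23 fell and 4 rose (24 and 4 adjusted over the list alone, camera adjusted p = 0.00684, adjusted p = 0.457 with an estimated correlation). NHL10-like Mapoly0010s0186 had a value of -1.48 ± 0.13.

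Of 62 cell cycle and histone genes 14 rose in Mpmycx and 7 fell (15 and 7 adjusted over the list alone, camera adjusted p = 0.0186, adjusted p = 0.594 with an estimated correlation). A CYCD4;1-like cyclin gene (Mapoly0030s0056, 0.56 ± 0.09) and a histone H2A gene (Mapoly0007s0080, 0.54 ± 0.07) rose most. Of 56 glycosyl- and methyltransferase genes 17 rose and 6 fell (21 and 6 adjusted over the list alone, camera adjusted p = 0.0371, adjusted p = 0.598 with an estimated correlation). OMT1-like Mapoly0129s0005 reached 1.04 ± 0.12. The largest increases included 5 genes similar to the proton pump AHA11, from 1.46 ± 0.14 (Mapoly0050s0045) to 1.64 ± 0.16 (Mapoly0050s0042). They are close relatives, and cross-hybridisation leaves each value uncertain. A tubby-like gene (Mapoly0170s0003) reached 1.70 ± 0.09 and a THIC-like gene of thiamine synthesis (Mapoly0078s0008) 1.31 ± 0.08.

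In limma's test 3742 genes differed between Mpmycx and Tak-2, 2088 lower and 1654 higher. Median centring gave 1860 and a fit of the 3 Mpmycx arrays alone 2293, and the glycosyl- and methyltransferase call ended with the submitters' ratios (adjusted p = 0.056, range over the scalings 0.0202 to 0.056). Higher genes made up 44.2% of the calls, 59.4% with the scanner software's ratios and 63.9% with the submitters' ratios.

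Effects of Mpmycy and Mpmycx under OPDA overlapped and were then tested against each other. The calls shared 966 lower genes (222 for independent lists of those sizes) and 357 higher genes (102), and 109 genes had opposite directions. Of falls of 2-fold or more, 255 genes had them in both mutants, with 9.6 for independent lists. Across the 13468 genes the log2 ratios of the mutants correlated with Pearson r = 0.758 and Spearman rho = 0.372, a description across genes, which are not independent replicates. The JAZ1-like gene showed a difference, Mpmycx minus Mpmycy, of -0.07 ± 0.12 (n = 6, adjusted p = 0.778). In contrast, CCD1-like Mapoly0066s0017 fell further in Mpmycy (-4.91) than in Mpmycx (-2.67), with a difference of 2.24 ± 0.20 (adjusted p = 0.00113).

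Nutrient transport genes were among those with different effects in the mutants. The nitrogen, sulfur, phosphate and iron list lay lower in Mpmycx than in Mpmycy (19 of 106 lower and 9 higher, 33 and 13 adjusted over the list alone, camera adjusted p = 0.0026, adjusted p = 0.848 with an estimated correlation). The NRT2.1-like gene differed by -2.72 ± 0.20 (-2.76 in Mpmycx and -0.04 in Mpmycy) and NRT3.1-like Mapoly1609s0001, a match to a partner protein of nitrate transporters, by -1.55 ± 0.15. A CAX2-like gene for a vacuolar cation exchanger (Mapoly0030s0112) differed by -3.23 ± 0.23, from -2.60 in Mpmycx and 0.63 in Mpmycy. In Mpmycy itself the nutrient list (16 lower and 5 higher, adjusted p = 0.376), the WRKY and AP2/ERF list (3 and 3, 0.896) and the dirigent list (9 and 5, 0.602) had not passed. The WRKY and AP2/ERF list (8 of 35 lower and 0 higher, 11 and 0 adjusted over the list alone, camera adjusted p = 0.0026, adjusted p = 0.813 with an estimated correlation) and the dirigent list (10 of 33 lower and 1 higher, 12 and 2 adjusted over the list alone, camera adjusted p = 0.00298, adjusted p = 0.848 with an estimated correlation) were also lower in Mpmycx relative to Mpmycy. WRKY42-like Mapoly0039s0030 differed by -2.01 ± 0.31 (adjusted p = 0.00849, range over 18 alternatives 0.000175 to 0.0513, the last with the scanner software's ratios) and dirigent gene Mapoly0135s0043 by -2.61 ± 0.41. So was the list of calcium and wound signalling kinases, which holds mostly leucine-rich repeat receptor-like kinases (5 of 79 lower and 0 higher, the same adjusted over the list alone, camera adjusted p = 0.0026, adjusted p = 0.577 with an estimated correlation). These counts depended on the scaling. With the scanner software's ratios the nutrient, WRKY and AP2/ERF, dirigent and kinase lists had 17, 1, 4 and 3 genes lower and 5, 0, 1 and 0 higher. With median centring they had 12, 1, 2 and 0 lower and 3, 0, 0 and 0 higher.

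The peroxidase list had not passed in Mpmycx itself (47 of 174 lower and 29 higher, adjusted p = 0.411), while it was lower in Mpmycy. In the direct test its genes lay higher in Mpmycx relative to Mpmycy (38 of 174 higher and 15 lower, 60 and 23 adjusted over the list alone, camera adjusted p = 0.0026, adjusted p = 0.848 with an estimated correlation). Mapoly0282s0001 had a difference of 1.77 ± 0.13 (0.64 against -1.13). The peroxidase list had 23 genes higher and 9 lower with the scanner software's ratios and 21 and 4 with median centring. Glycosyl- and methyltransferase genes also lay higher in Mpmycx (7 of 56 higher and 1 lower, 8 and 2 adjusted over the list alone, camera adjusted p = 0.0339, adjusted p = 0.848 with an estimated correlation). The latter call ended with median centring (2 higher and 0 lower, adjusted p = 0.07, range over the scalings 0.0267 to 0.07). Xyloglucan-modifying XTH genes of the cell wall went apart: XTH16-like Mapoly0149s0003 differed by 1.86 ± 0.22 and XTH25-like Mapoly0203s0007 by -2.32 ± 0.19. The proton pump gene Mapoly0050s0042 differed by 1.95 ± 0.22 and the ankyrin gene Mapoly0035s0005 by -1.82 ± 0.12. Together 1267 genes had different effects, 653 higher and 614 lower in Mpmycx relative to Mpmycy. This count was 632 with the scanner software's ratios, 416 with median centring and 835 without a dye term, and without Mpmycy replicate 1, 2 or 3 or Mpmycx replicate 1 it was 373, 629, 411 and 827. Mutant, sex and wild type accession change together here and cannot be told apart.

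**Figure D2:**
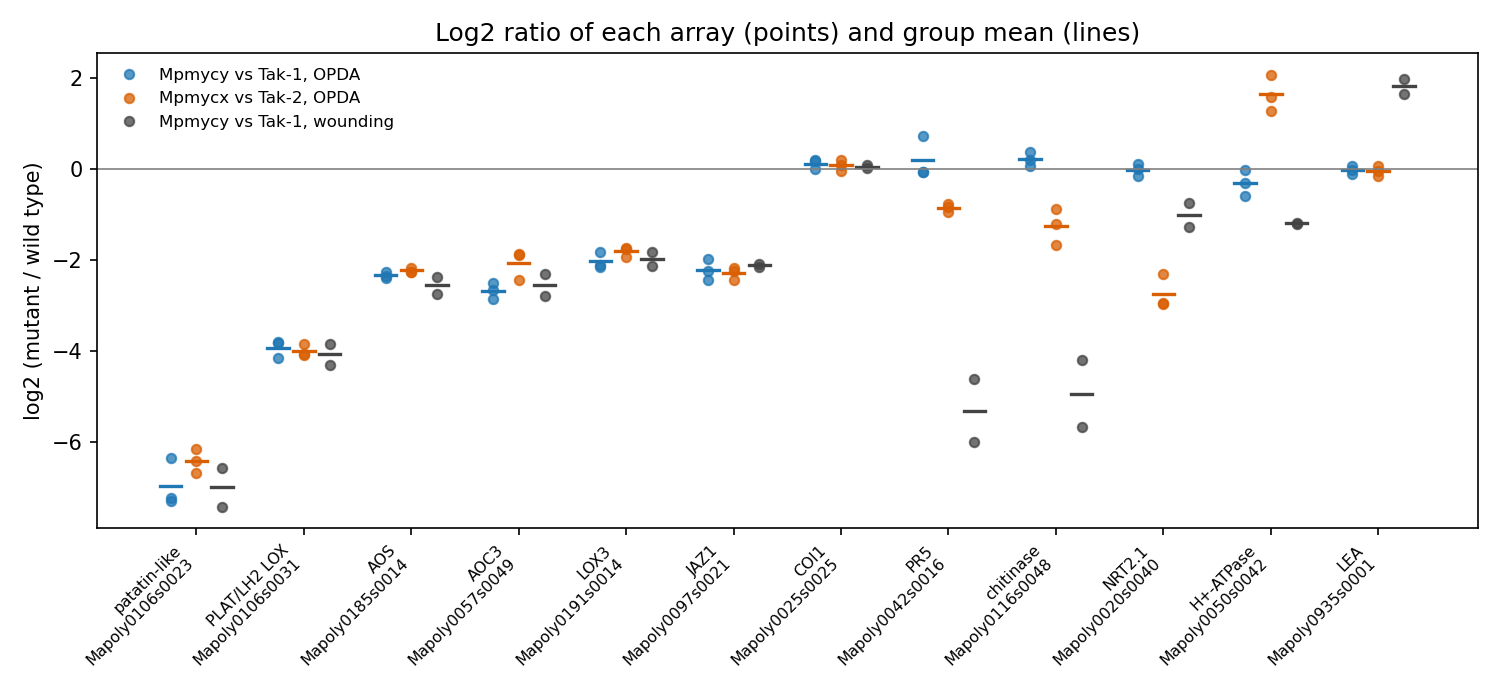
The vertical axis gives log2 ratios of mutant over wild type, with a point for each array and a line for the mean of each of the 3 groups, for 12 genes named in the text. Jasmonate biosynthesis genes and the JAZ1-like gene lie below 0 in all groups and the COI1-like gene near 0, whereas the PR5-like and chitinase genes lie lowest after wounding and the NRT2.1-like gene lies lowest in Mpmycx.

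Wounded Mpmycy was compared with wounded Tak-1 to ask which transcript levels depended on the male MYC gene after mechanical damage. The patatin-like gene Mapoly0106s0023 (-6.98 ± 0.25, n = 2, adjusted p = 9.34e-07) fell 127-fold, the cupin gene Mapoly0377s0002 113-fold and the chalcone synthase gene Mapoly0070s0036 87.1-fold. Defence genes fell steeply: PR5-like Mapoly0042s0016, a match to an antifungal thaumatin-like protein, fell 39.5-fold and the basic chitinase gene Mapoly0116s0048 30.5-fold. A peroxidase gene (Mapoly0220s0001) was at least 43.3-fold lower (adjusted p = 2.62e-06). LEA genes rose by up to 1.82 ± 0.09 (Mapoly0935s0001). In all, 777 genes were lower by 2-fold or more and 90 higher.

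Of 174 defence genes 105 fell after wounding and 8 rose (113 and 11 adjusted over the list alone, camera adjusted p = 4.25e-14, adjusted p = 0.338 with an estimated correlation). The chitinase gene Mapoly0218s0010 was among them (-4.55 ± 0.23). Of 174 peroxidase genes 114 fell and 5 rose (118 and 7 adjusted over the list alone, camera adjusted p = 1.55e-15, adjusted p = 0.338 with an estimated correlation). RCI3-like Mapoly0015s0156 fell steeply (-5.24 ± 0.15, mutant signal well above background on 1 of 2 arrays). Of 67 phenylpropanoid and flavonoid genes 46 fell and 4 rose (48 and 4 adjusted over the list alone, camera adjusted p = 1.19e-11, adjusted p = 0.338 with an estimated correlation). CAD9-like Mapoly0032s0158 was at least 17.4-fold lower. Of 33 dirigent, laccase and polyphenol oxidase genes 20 fell and 0 rose (21 and 0 adjusted over the list alone, camera adjusted p = 2.57e-07, adjusted p = 0.338 with an estimated correlation). Dirigent genes Mapoly0135s0043 and Mapoly0062s0101 stood at -3.49 ± 0.36 and -3.34 ± 0.14. Of 127 cytochrome P450 genes 58 fell and 11 rose (61 and 12 adjusted over the list alone, camera adjusted p = 0.000126, adjusted p = 0.338 with an estimated correlation). Mapoly0033s0061, similar to the CYP90 family, stood at -4.11 ± 0.11.

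The jasmonate biosynthesis list was lower after wounding as well, with 14 of 26 genes lower and 4 higher (the same adjusted over the list alone, camera adjusted p = 0.00363, adjusted p = 0.338 with an estimated correlation). The LOX3-like gene Mapoly0026s0148 stood at -5.19 ± 0.19, the lipoxygenase gene Mapoly0106s0031 at -4.06 ± 0.13, the AOS-like gene at -2.55 ± 0.08, the AOC3-like gene at -2.54 ± 0.13 and the JAZ1-like gene at -2.11 ± 0.11. The COI1-like gene had a value of 0.05 ± 0.08 (adjusted p = 0.67). A chlorophyllase gene (Mapoly0008s0176), for an enzyme that removes the phytol tail of chlorophyll, fell by 5.35 ± 0.14 on the log2 scale. The bHLH list did not pass (11 of 32 lower and 9 higher, adjusted p = 0.735), while Mapoly0013s0167 was at -2.67 ± 0.12 and the TT8-like gene at -3.88 ± 0.37.

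Of the 74 abscisic acid and desiccation genes 37 rose in wounded Mpmycy and 7 fell (37 and 9 adjusted over the list alone, camera adjusted p = 4.03e-07, adjusted p = 0.165 with an estimated correlation). Most of the risers were LEA genes, which encode protectants against drying. Of 134 heat-shock and chaperone genes 38 rose and 13 fell (39 and 13 adjusted over the list alone, camera adjusted p = 0.00912, adjusted p = 0.644 with an estimated correlation). HSP20-like Mapoly0075s0028 rose most (1.38 ± 0.17). Of 62 cell cycle and histone genes 13 rose and 3 fell (11 and 3 adjusted over the list alone, camera adjusted p = 0.00912, adjusted p = 0.644 with an estimated correlation). Over the 4 other scalings 5 to 29 of them rose and 1 to 3 fell, and the list passed in each. A SET7/9 methyltransferase gene (Mapoly0001s0505, 0.96 ± 0.07) and a histone H2A gene (Mapoly0007s0226, 0.78 ± 0.08) rose most. Other increases were those of the iron reductase gene FRO6-like Mapoly0047s0055 (1.90 ± 0.08), the glucosyltransferase gene UGT73C7-like Mapoly0069s0040 (1.82 ± 0.19) and PHT2;1-like Mapoly0054s0123 (1.65 ± 0.12).

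In limma's test 4681 genes differed after wounding, 2643 lower and 2038 higher. Median centring gave 2597, the 2 wounding arrays alone 2310 and the fit without replicate 1, which leaves 1 array, 2220. Higher genes made up 43.5% of the calls, 60.8% with the scanner software's ratios, which moved the median of all genes from -0.004 to 0.109, and 66.0% with the submitters' ratios.

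The effects of Mpmycy after wounding and under OPDA shared 933 lower calls (281 for independent lists), 444 higher calls (126) and 240 falls of 2-fold or more (17.9), and 144 genes had opposite directions. The log2 ratios correlated across genes with Pearson r = 0.589 and Spearman rho = 0.409. Mpmycx under OPDA and wounded Mpmycy shared 1168 lower (410) and 573 higher calls (250) and 302 falls of 2-fold or more (24.1), with 357 opposite calls, r = 0.601 and rho = 0.358. Falls of 2-fold or more in all 3 comparisons were seen for 213 genes, of 921 with such a fall in any.

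Under OPDA the defence list had not passed in Mpmycy (32 of 174 lower and 7 higher, adjusted p = 0.147, but 0.0415 with the scanner software's and 0.0189 with the submitters' ratios, range over the scalings 0.0189 to 0.33) or in Mpmycx (40 lower and 27 higher, adjusted p = 0.876, range over the scalings 0.338 to 0.975). The balance in Mpmycx was not stable, with 29 lower and 29 higher for the scanner software's ratios, 18 and 25 for median centring and 34 and 41 for the submitters' ratios. Tested directly, defence genes had lower values in Mpmycy after wounding than under OPDA (74 of 174 lower and 1 higher, 84 and 6 adjusted over the list alone, camera adjusted p = 4.15e-13, adjusted p = 0.399 with an estimated correlation). PR5-like Mapoly0042s0016 stood at -5.30 after wounding and 0.25 under OPDA, a difference of -5.56 ± 0.38 (n = 5, adjusted p = 0.000146). The chitinase gene Mapoly0116s0048 differed by -5.22 ± 0.35 and PR4-like Mapoly0040s0024 by -4.97 ± 0.44. Peroxidase genes (58 lower and 8 higher, 65 and 10 adjusted over the list alone, camera adjusted p = 3.31e-08, adjusted p = 0.479 with an estimated correlation) and phenylpropanoid and flavonoid genes (37 lower and 2 higher, 39 and 2 adjusted over the list alone, camera adjusted p = 3.14e-09, adjusted p = 0.399 with an estimated correlation) showed the same direction. Over the 4 other scalings 31 to 58 peroxidase genes were lower and 2 to 10 higher. PAL4-like Mapoly0044s0114, similar to the enzyme that opens the phenylpropanoid pathway, differed by -2.89 ± 0.13. Dirigent, laccase and polyphenol oxidase genes did so too (19 lower and 2 higher, 19 and 3 adjusted over the list alone, camera adjusted p = 1.09e-06, adjusted p = 0.443 with an estimated correlation). Over all lists and other genes, 461 were lower by a further 2-fold or more after wounding. Tak-1 was well above background on all 3 OPDA arrays for 363 of them. For 244 its level left room for a fall as large as after wounding. Where Tak-1 signal is low, a small value under OPDA therefore does not show independence of the MYC gene.

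Further lists with lower values after wounding than under OPDA were the calcium and wound signalling kinases (23 lower and 1 higher, 24 and 4 adjusted over the list alone, camera adjusted p = 0.0323, adjusted p = 0.399 with an estimated correlation), P450 genes (31 lower and 11 higher, 40 and 15 adjusted over the list alone, camera adjusted p = 0.0225, adjusted p = 0.479 with an estimated correlation) and glycosyl- and methyltransferase genes (11 lower and 0 higher, the same adjusted over the list alone, camera adjusted p = 0.0323, adjusted p = 0.479 with an estimated correlation). The calls of the P450 and glycosyl- and methyltransferase lists ended with the scanner software's ratios (adjusted p = 0.0648, range over the scalings 0.00708 to 0.0648, and 0.0573, range 0.0141 to 0.0573). The kinases had 14 genes lower and 0 higher with those ratios and 7 and 0 with median centring. Abscisic acid and desiccation genes had higher values after wounding (34 higher and 2 lower, 38 and 4 adjusted over the list alone, camera adjusted p = 7.77e-11, adjusted p = 0.0667 with an estimated correlation). The LEA genes Mapoly0935s0001 and Mapoly0119s0010 differed by 1.85 ± 0.12 and 1.64 ± 0.14, and CCD1-like Mapoly0066s0017 by 3.77 ± 0.22, since it fell less after wounding (-1.14 against -4.91). The JAZ1-like gene differed by 0.12 ± 0.14 (adjusted p = 0.612).

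In limma's test 2478 genes had different effects in the wounding and OPDA experiments, 1384 lower and 1094 higher after wounding, and the higher share of 44.1% was 54.7% with the submitters' ratios. Median centring gave 1048 genes, and fits without OPDA replicate 1 or 3 or wounding replicate 1 gave 1503, 1443 and 1003. The experiments also differed in plant age, 15 against 21 days, and in liquid against solid medium, which cannot be told apart from the treatment.

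**Figure D3:**
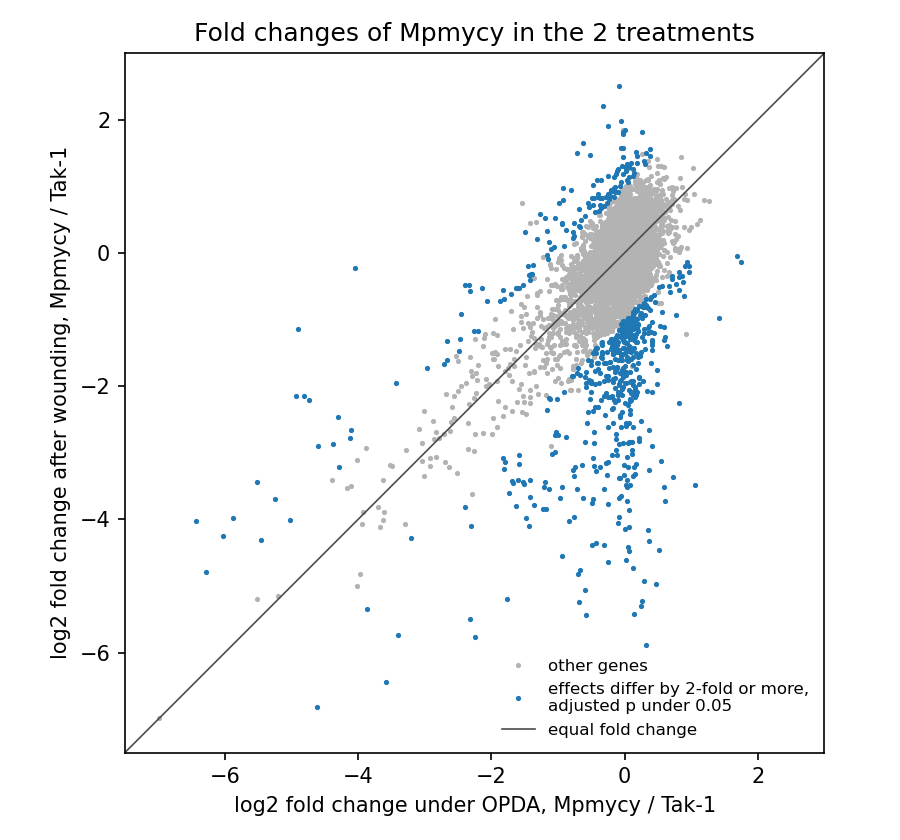
The horizontal axis gives the log2 fold change of Mpmycy over Tak-1 under OPDA and the vertical axis that after wounding, with a point per gene and a line of equal values. Blue points are the 618 genes whose effects differ by 2-fold or more with an adjusted p under 0.05, 461 of them lower after wounding, and values of genes below background are drawn as measured.

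No list of markers of other cells passed in a comparison with the wild type. Of 6 rhizoid genes 1 was lower in Mpmycy under OPDA, 2 were lower and 1 higher in Mpmycx, and 1 was higher after wounding (adjusted p = 0.309, 0.925 and 0.588). The sperm list matched 4 dynein light chain genes, too few for the test, of which 1, 1 and 2 were lower and 0, 0 and 1 higher. The list meant for RNA quality matched 22 nuclear photosystem II genes and no organelle transcript, with 2, 1 and 4 higher and 0, 1 and 0 lower (adjusted p = 0.101, 0.876 and 0.424). The jasmonate signalling list held 11 genes, among them potassium channels and GATA-type ZIM genes that the search words had also matched, and did not pass either (2 lower and 1 higher, 3 and 1, and 1 and 1, adjusted p = 0.3, 0.411 and 0.935).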

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

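The tests of dye bias and of normalization were chosen after the share of lower genes had been seen, and the other tests in this part before their results. No group held the 4 arrays needed to look for an array far from the others.

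Changes of 2-fold or more were mostly falls in every comparison with the wild type: 96.6% of such calls in Mpmycy under OPDA, 87.6% in Mpmycx and 89.6% after wounding. A dye bias would have reversed this between the dye orientations, but at least 84.3% of the genes 2-fold or more apart were lower in each orientation and group. Over 5 sources of values, among them the submitters' ratios, the lowest share was 72.1%, with the scanner software's ratios after wounding, which argues against normalization as the whole cause. With each Arabidopsis match counted once the lowest share was 87.2%, so that copies with the same match do not account for it. Related genes with different matches still count separately there, and genes without a match were left out (576 of the 777 lower genes after wounding were used). Cross-hybridisation within wider families is therefore not excluded. A candidate explanation is that the wild type MYC genes raise many transcripts in both treatments, a hypothesis drawn from the same data that was not itself tested.

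The fall in Mpmycy was larger after wounding than under OPDA for many genes: the effects differed for 2478 genes, a test of the difference itself, and 461 were lower by a further 2-fold or more. For 363 of these 461 (78.7%) Tak-1 was well above background on all 3 OPDA arrays, and for 244 (52.9%) its level left room for a fall as large as after wounding, which lies between the bounds set beforehand and leaves open that low wild type signal limits the fall under OPDA for the rest. The Tak-1 level of these genes was higher on the wounding arrays by a median of 1.74 on the log2 scale (SD 1.32, 442 of 461 genes), against 0.02 in the mutant and -0.03 over all genes. The genes were chosen by the difference in ratio, so that a gap of this kind between the genotypes was built in. The choice alone did not fix that Tak-1, and not the mutant, held the shift. For genes without room, however, a mutant signal near the background can hardly shift, so that the choice favoured a shift in Tak-1. The 244 genes with room were not examined apart, so how far this made the gap is unknown. The Tak-1 and mutant levels are single channels compared across arrays, with unbalanced dye swaps under OPDA. The higher Tak-1 level could reflect induction by wounding, which the mutant lacks, or the plants' age and medium, which differ in the same way. It could also reflect an effect of OPDA itself, since no array of untreated plants gave a baseline. The length of treatment may differ too, 3 h under OPDA by the design text against 2 h after wounding. These cannot be told apart. With 2 wounding arrays no other split of the arrays was counted.

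The effects of Mpmycx and Mpmycy under OPDA differed for 1267 genes, also by a test of the difference, and for 222 by 2-fold or more. Of these 222, 0 (0%) lay on the Y chromosome or on the scaffolds detected on Tak-2 arrays, so sex-chromosome probes do not account for the set. A channel was well above background on all 6 arrays for 205 (92.3%), so signal lost in both channels does not account for most of it. Whether a wild type level near the background limited the fall in 1 of the mutants was not tested. The 144 annotated genes had 87 different Arabidopsis matches (60.4%), which leaves open that signal shared within families makes the set look larger. Of the 10 splits of the 6 arrays into 3 and 3, only the real one (1 split) gave as many genes and the highest other gave 3, but 10 splits are too few for a share under 0.05. MYC gene, sex and accession change together, so whether the mutants, the sexes or the wild types differ could not be tested.

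For the comparisons with the wild type, turning the sign of 1 array gave 4 splits each. In Mpmycy under OPDA the real one (1 split) gave 2261 genes and the highest other 0, and in Mpmycx they gave 3742 and 0, and 4 splits are too few for a share under 0.05.

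Several named genes were singled out because their effects in the mutants differed under OPDA in a direct test (Mpmycx minus Mpmycy, n = 6). CCD1-like Mapoly0066s0017 differed by 2.24, proton pump gene Mapoly0050s0042 by 1.95, XTH16-like Mapoly0149s0003 by 1.86 and peroxidase gene Mapoly0282s0001 by 1.77. Transport genes on the other side were CAX2-like Mapoly0030s0112 at -3.23, NRT2.1-like Mapoly0020s0040 at -2.72 and NRT3.1-like Mapoly1609s0001 at -1.55. Also lower in Mpmycx relative to Mpmycy were WRKY42-like Mapoly0039s0030 at -2.01, dirigent gene Mapoly0135s0043 at -2.61 and XTH25-like Mapoly0203s0007 at -2.32. So was ankyrin gene Mapoly0035s0005 at -1.82, which rose in Mpmycy.

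Further genes were singled out because Mpmycy had different effects after wounding and under OPDA in a direct test (wounding minus OPDA, n = 5). Defence genes led: PR5-like Mapoly0042s0016 differed by -5.56, chitinase gene Mapoly0116s0048 by -5.22 and PR4-like Mapoly0040s0024 by -4.97. Phenolic metabolism genes were PAL4-like Mapoly0044s0114 at -2.89 and dirigent gene Mapoly0135s0043 at -4.55, and LOX3-like Mapoly0026s0148 stood at -3.43. For peroxidase gene Mapoly0220s0001 and CAD9-like Mapoly0032s0158 the fitted differences were -4.86 and -4.14, but the mutant was not well above background on either wounding array, so that these are no exact sizes and only the bounds on the falls after wounding hold. Differences in the other direction were those of CCD1-like Mapoly0066s0017 (3.77), PHT2;1-like Mapoly0054s0123 (2.28), FRO6-like Mapoly0047s0055 (2.16) and the LEA genes Mapoly0935s0001 (1.85) and Mapoly0119s0010 (1.64).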

How the results depend on the processing

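Of 1963 recomputed values for 138 named gene effects, 1953 kept their direction and their side of the threshold, 10 kept the direction and lost the call, and 0 reversed. The 10 belong to 3 genes: BRK1-like Mapoly0132s0041 in Mpmycy under OPDA (2 of 14 alternatives, values 0.51 to 0.73), Mapoly0018s0019 in Mpmycx (7 of 13, -0.35 to -0.15) and WRKY42-like Mapoly0039s0030 between the mutants (1 of 18, -2.42 to -1.77). Most named genes were chosen as called genes with large changes, so that this stability was largely built in. It does not speak for the calls as a whole. Counts of genes are given below in the order Mpmycy under OPDA, Mpmycx under OPDA, wounding, between the mutants and between the treatments. Of 16, 16, 15, 20 and 19 alternatives, 10, 12, 10, 11 and 13 kept these counts within 1.5 times. No background subtraction, no filter, the stricter filter, array weights, the mean of probes, the submitters' ratios and separate channels did so in each. The order of the mutants' counts under OPDA was less stable. Mpmycy had 2261 genes and Mpmycx 3742, but 3248 and 2873 with array weights and 2666 and 2293 with the compared arrays alone. The weights were 0.96 to 2.54 for the Mpmycy OPDA arrays and 0.58 to 1.06 for the other arrays. The alternatives were fixed before the data were examined, and slide or scan as a block was not run because there was 1 of each. Signal over background limits what the dimmer genotype can show, since falls to the background are bounds.

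Median centring in place of loess gave 1042, 1860, 2597, 416 and 1048 genes. The scanner software's ratios gave 632 between the mutants and no dye term 835, and the compared arrays alone gave 2293 in Mpmycx and 2310 after wounding. The cause was not tested. By construction, a change of 2-fold or more left 322, 476, 867, 222 and 618 genes and an adjusted p under 0.01 left 1207, 2089, 2943, 344 and 1165. Leaving out an array gave 989 to 1209, 2504 to 3283, 2220 to 3237, 373 to 1050 and 1003 to 1932 genes, with fewer arrays in each fit. The lowest of these were without Mpmycy OPDA replicate 2, which is the dye-swapped array, in the first range, and without wounding replicate 1 after wounding and between the treatments, where the remaining wounding array is assumed to vary like the other groups. Between the mutants it was 373, 629 and 411 without Mpmycy replicate 1, 2 and 3 and 827 without Mpmycx replicate 1, and between the treatments 1503 and 1443 without OPDA replicate 1 and 3.

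With the replicate number as a block in place of the dye term, 1035 genes differed between the mutants and 1961 between the treatments, and no call of a named gene changed with the pairing.

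Of the lists, 7, 9, 9, 6 and 8 passed. With an estimated correlation 0, 0, 0, 0 and 0 did, and with fry, which asks whether a list moves one way without comparing it with other genes, 16, 20, 19, 0 and 15. Without OPDA replicate 2, 5 passed between the treatments, where leaving out an array gave 5 to 8. Of 39 list calls 33 held under the 4 other scalings, 6 were lost in at least 1 and 0 reversed, and 6 lists that had not passed did so under at least 1: P450 genes, defence genes and cell wall genes in Mpmycy under OPDA, P450 genes and ABC and MATE transporters in Mpmycx, and heat-shock genes between the treatments. Which of higher and lower calls were more numerous turned under at least 1 scaling for 1 of the 39 (heat-shock genes in Mpmycy under OPDA) and for 32 of the 106 lists that had not passed. The median, mean and test differed in sign for 3, 6, 6, 6 and 3 lists, 0 of which had passed.

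The correlation across genes of the mutants under OPDA was 0.685 with the scanner software's ratios and 0.702 to 0.764 with an array left out. That of Mpmycy under OPDA and after wounding was 0.525 to 0.625 with an array left out. That of Mpmycx and wounded Mpmycy was 0.528 with the scanner software's ratios and 0.563 to 0.606 with an array left out.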

Other observations

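The stricter test of neighbouring genes was added after its first result had been seen, and the other tests in this part were set before their results.

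Genes outside the groups described so far also fell in all 3 comparisons. A GH3-like gene (Mapoly0053s0073), from a family of enzymes that join amino acids to acidic hormones, had values of -4.11 ± 0.07 in Mpmycy under OPDA, -3.87 ± 0.07 in Mpmycx (n = 3 each) and -3.50 ± 0.09 in wounded Mpmycy (n = 2). IAMT1-like Mapoly0092s0080, a match to a methyltransferase of the auxin indole-3-acetic acid, stood at -4.02 ± 0.10, -3.29 ± 0.10 and -5.00 ± 0.12. The auxin list of 44 genes as a whole did not pass, with 6, 7 and 11 genes higher and 10, 11 and 10 lower (adjusted p = 0.309, 0.411 and 0.877). A starch synthase gene (Mapoly0148s0026) had values of -2.34 ± 0.05, -2.01 ± 0.05 and -2.27 ± 0.06, while the list of 52 starch and sugar genes did not pass (3, 8 and 13 higher, 8, 16 and 16 lower, adjusted p = 0.232, 0.447 and 0.877).

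A MATE-type transporter gene (Mapoly0005s0170) had values of -2.56 ± 0.05, -2.86 ± 0.05 and -2.48 ± 0.06 in the same order, and a GDSL lipase gene (Mapoly0016s0185) of -3.52 ± 0.07, -3.27 ± 0.07 and -3.18 ± 0.09. Their lists did not pass: of 43 ABC and MATE transporter genes 4, 4 and 8 were higher and 10, 15 and 14 lower (adjusted p = 0.174, 0.0925 and 0.813, with a range over the scalings of 0.0402 to 0.113 in Mpmycx, where median centring and the submitters' ratios gave a call), and of 61 lipid transfer, wax and cutin genes 10, 14 and 13 were higher and 10, 11 and 13 lower (adjusted p = 0.587, 0.739 and 0.652). ELIP-like Mapoly0004s0163, a match to an early light-induced protein of the thylakoid, stood at -2.49 ± 0.06, -3.33 ± 0.06 and -1.48 ± 0.07, in a list of 99 photosystem and light-harvesting genes of which 5, 10 and 6 were higher and 3, 13 and 13 lower (adjusted p = 0.304, 0.925 and 0.534). An expansin gene of cell wall loosening (Mapoly0125s0001) was at -2.24 ± 0.10 in Mpmycy and -2.63 ± 0.10 in Mpmycx under OPDA, and of 117 cell wall genes 9, 23 and 19 were higher and 20, 24 and 29 lower (adjusted p = 0.174, 0.876 and 0.534). In Mpmycy under OPDA the cell wall list passed with the scanner software's ratios (0.0415, range over the scalings 0.0415 to 0.201).

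In Mpmycx 36 of 127 P450 genes were lower and 19 higher (adjusted p = 0.158, range over the scalings 0.0428 to 0.237, the lowest with the scanner software's ratios). Further lists did not pass in any comparison with the wild type. Of 14 chlorophyll and carotenoid genes 0, 2 and 3 were higher and 5, 3 and 4 lower (adjusted p = 0.0725, 0.925 and 0.877), of 22 MYB genes 2, 1 and 6 higher and 4, 3 and 4 lower (0.807, 0.988 and 0.588) and of 17 terpenoid genes 0, 1 and 4 higher and 2, 2 and 4 lower (0.376, 0.411 and 0.813). Of 76 oxidative-stress genes 8, 13 and 15 were higher and 6, 14 and 13 lower (0.423, 0.722 and 0.546), and of 187 ribosomal protein genes 5, 7 and 12 were higher and 1, 16 and 14 lower (0.376, 0.925 and 0.877). The balance of the ribosomal calls turned with the scaling. In Mpmycx 19 were higher and 9 lower with the scanner software's ratios, 3 and 0 with median centring and 30 and 6 with the submitters' ratios. After wounding these were 14 and 3, 5 and 0, and 38 and 3.

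Lists described elsewhere also failed to pass in some comparisons. In Mpmycy under OPDA these were the calcium and wound signalling kinases (5 higher and 4 lower, adjusted p = 0.0737), cell cycle and histone genes (9 and 3, 0.109) and glycosyl- and methyltransferase genes (6 and 8, 0.774). In Mpmycx they were the same kinases (2 and 15, 0.158) and heat-shock genes (16 and 11, 0.411). After wounding they were the kinases (12 and 28, 0.437), nutrient uptake genes (31 and 34, 0.768), WRKY and AP2/ERF genes (7 and 10, 0.813) and glycosyl- and methyltransferase genes (5 and 14, 0.123).

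The 213 genes lower by 2-fold or more in all 3 comparisons often carried consecutive locus numbers. They held 25 such pairs, with 2.31 expected and at most 9 in 10000 random sets of tested genes of that size (one-sided permutation p = 1e-04, the smallest these draws can give). Of the 25 pairs, 5 shared an Arabidopsis match, and tandem copies, which can share signal, could account for these. In 15 pairs at least 1 gene had no match, so that whether they are copies is unknown. The remaining 5 pairs had different matches, with 1.30 expected (permutation p = 0.0097). In the stricter test 3 pairs shared no word of their descriptions, with 1.22 expected (permutation p = 0.125), so that clusters of unrelated genes that change together remain an open hypothesis.

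Genes without an Arabidopsis match made up 67 of these 213 (31.5%) and 3267 of the other 13255 tested genes (24.6%), an odds ratio of 1.4 (two-sided Fisher's exact test, p = 0.025). Genes without a match were thus somewhat more frequent among the 213, which the hypothesis of liverwort-restricted genes predicts. No other plant was compared, so that whether these genes are restricted to liverworts was not tested. The test rests on the matches given with the array, and tandem copies among the 213 are not independent. In 15 of their 25 consecutive pairs at least 1 gene had no match, so that this p-value may be too small.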
